A study of Mus musculus with 33 samples.

How the data were processed

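H3K9me2 and Lamin B1 were profiled by CUT&RUN, with IgG as control, in 33 libraries. mES cells are a C57BL/6 line grown in LIF and 2 inhibitors (2i), and whole hearts and right forebrain lobes came from E11.5 embryos of C57BL/6 mice. Per the labels, each source had 3 biological replicates, which were pools of different litters for the tissues and different vessels for the cultured cells, and the CUT&RUN kit ranged over several versions. Per the submitters' processing notes, Trim Galore, cutadapt 4.2, Bowtie2 2.5.0, Picard and deepTools were used with the mm10 genome. How the domains were called from the libraries, with which thresholds and how IgG entered, is not given in the sources used here. Signal tracks named in the labels were not analysed here.

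The files used were the 9 lists of domains deposited by the authors. Each has 3 columns, chromosome, start and end, in whole bins of 10 kb, with no score. Each list pools the replicates of a source, so replicates could not be compared, the depth behind a domain is unknown, and no counting interval or floor could be given. The states LAD, KOD and open did not overlap within a source. Bins inside the span of a chromosome that were in no list were kept as such. A longer domain can come from a deeper library or a looser threshold as well as from chromatin, and bins with few mappable reads can drop out of every list or be placed by reads of near-identical copies.

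Maps were painted in bins of 10 kb over chromosomes 1 to 19 (2401 Mb, from the first to the last listed bin of each chromosome) with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Errors of shares, densities and overlaps are delete-one-chromosome jackknife standard errors. For differences of changed shares and of lost LADs the SE is that of the unweighted mean of the differences per chromosome. Differences of shares were tested with a two-sided sign-flip permutation test over the 19 chromosomes with 100000 resamples, and overlaps with 10000 circular shifts per chromosome. Benjamini-Hochberg adjustment was over 9 tests of shares, 9 of overlaps, 3 of changed shares and 6 of lost LADs. Chromosomes are pieces of 1 pooled map, so these tests say whether a difference holds along the genome and not whether it would hold in other animals or cultures. The tests, lists and alternatives were chosen before the data were examined unless named otherwise.

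Genes came from the RefSeq annotation of GRCm38.p6, the assembly that mm10 is made from. It had 20661 protein-coding genes on chromosomes 1 to 19. The table used carries no strand, so the start of transcription that the planned test needed could not be placed, and the state of a gene is the one that covers the largest part of its body, which can be under 50%, which had been planned as the alternative. The state at the gene midpoint was the same for 99.0%, 98.4% and 98.7% of genes in mES cells, heart and forebrain. No genome sequence was used, so GC content was not computed. The planned test over 20 chromosomes became one over 19, and leaving out chromosome X was void, since the lists used here cover no X.

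The 25 gene lists were fixed beforehand, as symbols for 13 lists and as name patterns for 12 families, namely pluripotency, cardiac contractile and conduction, cardiac transcription factors and signals, endothelial and endocardial, blood, forebrain transcription factors, neuronal, synaptic and axon guidance, neural crest, mesenchyme and skeletal muscle, liver and gut, germline, housekeeping, imprinted, H3K9 methylation and nuclear lamina, Hox, olfactory, vomeronasal and taste receptors, keratins, Zfp genes, clustered protocadherins, beta defensins, Cyp2, Cyp3 and Cyp4 genes, replication-dependent histones, ribosomal proteins, and interleukin, chemokine and interferon genes. Symbols were matched directly or through an unambiguous synonym, and 34 of 35 matched for liver and gut and all for the other lists. Some genes stand in 2 lists, such as Isl1, Sox17, Zfp42, Cyp3a11 and Rpl13a. A list counts as enriched or depleted in a state only if a two-sided Fisher exact test against all other protein-coding genes and a two-sided circular-shift permutation test both passed 0.05 after adjustment over 225 tests, in the same direction. Changes were tested with an exact two-sided sign test on genes and on switched regions, where genes in 1 contiguous switched region count once, both adjusted over 75 tests per state. A gap in no list can split a region, so 1 gene cluster can count more than once. Expression was not measured, so no state says whether a gene was active.

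Genes named in the text follow a rule set before the data were examined. For each pair of sources they are members of the symbol lists that were listed in both and differed in state, in list order with LAD changes first, at most 6 per list, then the 5 longest regions LAD in 1 source and open in the other with at most 3 genes wholly inside, and the longest domain of each list. Genes given as examples of a list's count (Myh6, Tnnt2, Ttn, Cntnap2, Csmd1 and Dlg2), genes that only touch a region (Ryr2, Ctnnd2, Dpp6, Vmn1r100, Vmn1r101 and the Zfp and Psg genes) and the vomeronasal genes of chromosome 7 as a group were chosen after their values were seen. Some genes that the rule or these examples would name are not reported here, though they stay in the counts and tests of their lists.

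For the closing part a tandem array is a run of at least 5 genes with the same name stem whose starts lie at most 200 kb apart, leaving out stems that name no family, a definition chosen after the results were seen. The statistics were tested on simulated data. Sign flips gave a p under 0.05 in 4% of 200 comparisons with no difference and in 100% with a difference of 1.2 SD, and overlap shifts in 5% of maps rolled apart. For a list of 40 scattered genes in the LADs of mES cells the Fisher and shift tests together passed in 0.5% of 200 lists, but for 40 genes in 5 runs of neighbours they passed in 17% (Fisher alone 40.5%), since the shift compares a list with places in the genome and not with other genes. Rotation of a list along the order of genes, added for this reason, passed in 2.5% and 1.5%, and every test found lists with 28 of 40 genes in LADs in 100% of cases. The sign test on regions passed in 0% of 50 scattered and 50 clustered lists and in 100% with 15 of 40 genes leaving. The 0% says little about its error rate. From mES cells to heart only 1003 of 20661 genes left the LADs and 530 entered them. A simulated list of 40 therefore usually holds too few switched regions to pass, unlike the larger families tested below. Alternatives were domains under 100 kb left out, 20 kb trimmed from domain ends, other denominators and null models, regions under 50 kb left out, domains 10 kb apart merged, other definitions of a gene's state, other backgrounds, and each chromosome left out in turn.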

Results

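CUT&RUN, which cuts and releases the DNA under an antibody in unfixed cells, was used to map dimethylation of histone H3 lysine 9 (H3K9me2) and the nuclear lamina protein Lamin B1 in mouse embryonic stem (mES) cells and in the heart and forebrain of E11.5 embryos. H3K9me2 is a mark of repressed chromatin, and lamina-associated domains (LADs) are the long stretches of chromatin that touch the nuclear envelope. The series holds 33 libraries in 9 groups. H3K9me2 and Lamin B1 each have 3 libraries in each of the 3 sources, and the IgG control has 6 in forebrain, 6 in heart and 3 in mES cells. The analysis rests on 9 lists of domains, 3 per source, which name each stretch as LAD, KOD or open. KOD is the depositors' own label and the sources used here do not spell it out. Each list pools the replicates, carries no score and covers chromosomes 1 to 19 of the mm10 genome in whole bins of 10 kb, and no bin was in more than 1 list of a tissue. The depth behind a domain is therefore unknown, and no value below has a replicate error. Errors are jackknife standard errors over the 19 chromosomes (n = 19) unless named otherwise, and they measure the spread along 1 pooled map, not between animals or cultures.

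Which part of the genome is in each state was asked first. LADs took up the most bases in every source, and the heart had the fewest of them and the most LAD domains. The longest LAD of mES cells spanned chromosome 8 from 95990001 to 104000000 and held the cadherin genes Cdh8 and Cdh11. That of the forebrain spanned chromosome 15 from 13210001 to 25300000, with Cdh12, Cdh18 and Cdh10, and that of the heart spanned chromosome 12 from 59270001 to 64890000, with Lrfn5, a gene of a synaptic adhesion protein. The longest KOD of mES cells was chromosome 16 from 5280001 to 8380000, where Rbfox1, a neuronal splicing factor, lay wholly inside. It was chromosome 6 from 31550001 to 34310000 in heart, with Exoc4 and Plxna4. In forebrain it was chromosome 5 from 131490001 to 134220000, with Castor2 and Gtf2ird2. The longest open domain was chromosome 10 from 79490001 to 82400000 in mES cells, with 142 protein-coding genes inside, chromosome 14 from 3050001 to 7710000 in heart, with 74, and chromosome 12 from 21500001 to 25270000 in forebrain, with 22.

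LADs covered 43.6% ± 1.47 of the 2401 Mb in mES cells, 40.1% ± 1.52 in heart and 44.0% ± 2.24 in forebrain. The heart value was lower than that of mES cells by a difference of -3.45 percentage points (SE 0.478, lower on 18 of 19 chromosomes, adjusted p = 0.00036, two-sided sign-flip permutation test) and lower than that of forebrain by -3.91 points (SE 1.04, lower on 17 of 19, adjusted p = 0.00733, same permutation test). Both differences depend on bases that are in no list of the heart, which made up 11.6% ± 0.718 of the heart map against 7.17% ± 0.333 in mES cells and 7.71% ± 0.354 in forebrain. Over bins listed in all 3 sources the heart differed by -0.148 points from mES cells and by 0.504 points, in the other direction, from forebrain (adjusted p = 0.78 for each, permutation test). KODs covered 17.5% ± 1.02, 18.5% ± 1.85 and 17.2% ± 1.94 in mES cells, heart and forebrain. Open domains covered 31.7% ± 1.10, 29.8% ± 0.865 and 31.1% ± 1.09. No difference in these passed the permutation test after adjustment over the 9 tests (lowest adjusted p = 0.0773). The lower open share of the heart did pass, against each other source, with domains under 100 kb left out and with 20 kb trimmed from domain ends. Both settings take more bases from a list with more, shorter domains, as that of the heart was, so they add no independent support.

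The heart LADs were also more broken up. Their number was 3522, with a median length of 90 kb, against 1932 of 160 kb in mES cells and 2085 of 120 kb in forebrain. LADs of at least 1 Mb held 43.7% of all LAD bases in heart, 66.6% in mES cells and 70.1% in forebrain. The heart also had more open domains, 4183 with a median of 100 kb, than mES cells, 3214 of 140 kb, and forebrain, 3730 of 110 kb. KOD numbered 2974, 2679 and 2620 in heart, mES cells and forebrain, with medians of 70, 80 and 70 kb. Among domains of at least 100 kb the LADs numbered 1740 in heart, 1182 in mES cells and 1177 in forebrain. There is 1 list per source, so these numbers have no test.

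**Figure D1:**
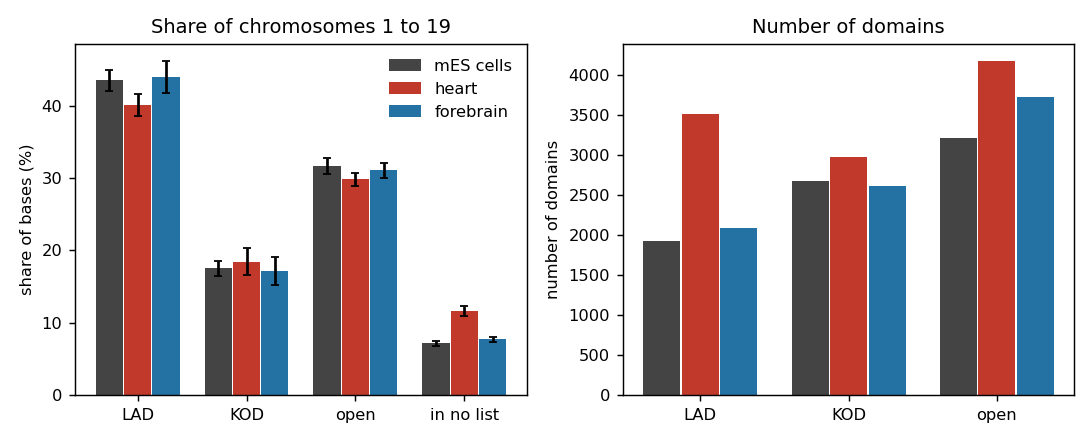
Share of the bases of chromosomes 1 to 19 in each state in percent (left, bars with jackknife standard errors over 19 chromosomes) and number of domains per list (right, no error), for mES cells, heart and forebrain. The heart has 40.1% of bases in LADs and 11.6% in no list, and 3522 LADs against 1932 and 2085.

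How far the maps overlap between sources was asked next. By bases LADs were the most alike and KODs the least, an order that other measures did not keep in every pair. The Jaccard index, bases shared over bases in either map, was 0.737 ± 0.0149 for LADs between mES cells and heart, 0.797 ± 0.0175 between mES cells and forebrain and 0.751 ± 0.0118 between forebrain and heart. For KODs the index was 0.446 ± 0.0179, 0.378 ± 0.0195 and 0.526 ± 0.0274 in the same order. For open domains it was 0.581 ± 0.00968, 0.557 ± 0.0105 and 0.619 ± 0.00812. Each of the 9 lay above all 10000 maps shifted along the chromosomes (adjusted p = 0.0001, one-sided permutation test, the smallest these shifts can give), where the highest shifted value was 0.362 for LADs, 0.191 for KODs and 0.226 for open domains. Counted as the share of domains of the first source with at least 50% of their length in the same state in the other, the values between forebrain and heart were 0.609 for LADs, 0.621 for KODs and 0.662 for open domains. With any shared bin they were 0.711, 0.692 and 0.745. In all 3 sources 811 Mb were LAD, which is 66.2% ± 1.81 of the bases that were LAD in any, compared with 28.3% ± 1.87 for KODs (192 Mb) and 44.0% ± 0.947 for open domains (458 Mb). Of the 1951 Mb listed in all 3 sources, 74.9% kept 1 state throughout.

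Of bases listed in both maps, 18.2% ± 1.09 had another state in heart than in mES cells, 19.2% ± 1.28 in forebrain than in mES cells, and 14.9% ± 0.827 in heart than in forebrain. The 2 embryonic tissues differed less from each other than either did from mES cells, by -3.35 points for the heart (SE 0.735, lower on 18 of 19 chromosomes) and -4.36 points for the forebrain (SE 0.899, lower on 17 of 19), each with an adjusted p = 9e-05 in the two-sided permutation test. When bins in no list counted as a state of their own, the second of these differences was -1.75 points (adjusted p = 0.0955, permutation test). The SE of each difference between pairs is that of the unweighted mean over chromosomes, not a jackknife. Exchange between KOD and open made up 59.2% of the changed bases between mES cells and heart, 67.9% between mES cells and forebrain and 55.8% between forebrain and heart. Exchanges of LADs with KOD and with open were not fewer between the 2 tissues than between mES cells and forebrain. They were 74.0 and 58.6 Mb between forebrain and heart and 72.8 and 56.9 Mb between mES cells and forebrain. Between mES cells and heart they were 86.5 and 64.3 Mb. From mES cells to heart 135 Mb went from open to KOD and 84.1 Mb from KOD to open, and from mES cells to forebrain 134 Mb and 140.5 Mb did so. The most common pattern with a change was open in mES cells and KOD in both tissues, 84.1 Mb, followed by KOD in mES cells and open in both, 64.0 Mb. The exchange was uneven between chromosomes. On chromosome 11 KOD covered 21.4% of bases in mES cells, 39.3% in heart and 39.0% in forebrain, and on chromosome 19 21.1%, 44.1% and 33.7%. On chromosomes 3, 6, 8, 10, 12 and 13 the KOD share was lower in both tissues than in mES cells.

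**Figure D2:**
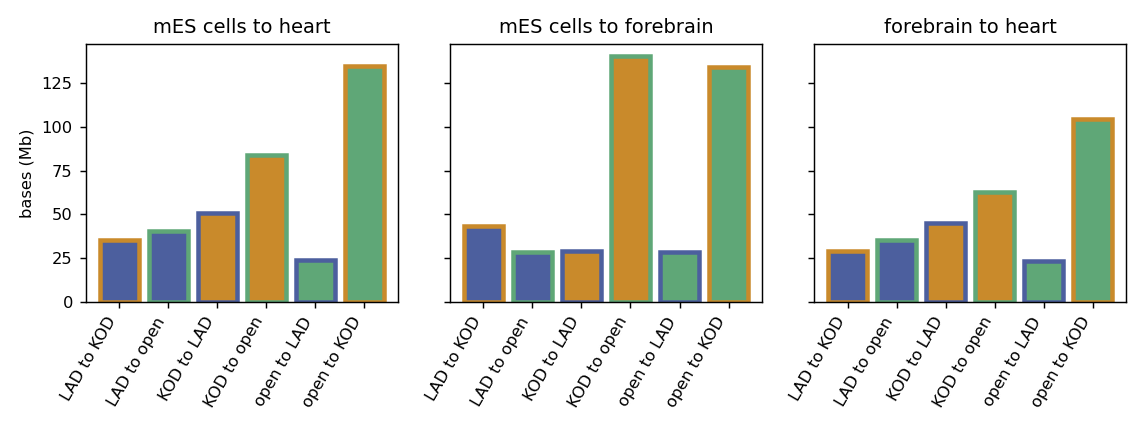
Bases in Mb that differ in state between 2 sources, for the 3 pairs. The fill of a bar gives the state in the first source and its outline the state in the second, and KOD to open or open to KOD is the tallest bar in every pair, such as 134.94 Mb from open to KOD between mES cells and heart.

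Between mES cells and heart, genes of heart muscle contraction and of red blood cells were among those that were LAD in mES cells and open in heart. Actc1, cardiac actin (chromosome 2, 114047282 to 114052875), Ryr2, the calcium release channel of heart muscle (chromosome 13, 11553099 to 12106945), and Slc8a1, the sodium-calcium exchanger (chromosome 17, 81373105 to 81738387), were LAD in mES cells, over 100%, 41.0% and 100% of the gene body, and open in heart over 100%, 98.2% and 100%. Nebl (68.1% LAD, then 42.7% open) and Corin, the natriuretic peptide convertase (83.1% and 70.7%), did the same by the state that covers the largest part of the gene. The midpoints of Ryr2, Nebl and Corin did not show this change. The transcription factors Isl1 (chromosome 13, 116298270 to 116309688) and Mef2c also went from LAD to open. The beta-globin genes Hbb-bt, Hbb-bs, Hbb-bh1 and Hbb-y (chromosome 7, 103812524 to 103853207) and the liver genes Alb and Afp (chromosome 5, 90460870 to 90508907) were wholly LAD in mES cells and wholly open in heart. In the other direction Dppa2 and Dppa4, pluripotency genes on chromosome 16, were open in mES cells and LAD in heart, and Apob and Grin2b, a glutamate receptor subunit, were KOD in mES cells and LAD in heart.

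Counted by list, 6 cardiac contractile genes were LAD in mES cells and not in heart and 1, Myom2, was the reverse. In number of switched regions this is 6 against 1 (p = 0.125, exact two-sided sign test), and 3 regions against 0 of the cardiac transcription factor list left the LADs (p = 0.25, exact sign test). Among genes listed in all 3 sources, a set chosen after the results were seen, 5 of 9 contractile genes left the LADs. For other genes it was 13.3% (Fisher exact test, adjusted p = 0.0252, genes taken as independent). Of the cardiac contractile list 15 of 45 genes were KOD in mES cells and 9 in heart, among them Myh6, Tnnt2 and Ttn, KOD in mES cells and open in heart. From any other state 12 regions of the list became open and 3 ceased to be (exact sign test p = 0.0352, adjusted p = 0.195 over 75 tests). Of its 30 genes open in heart 14 were not open in mES cells, compared with 13.1% of other genes (Fisher exact test, adjusted p = 7.07e-05), and of its 26 genes open in forebrain 11 were not, compared with 15.2% (Fisher exact test, adjusted p = 0.0046). Both held among genes listed in all 3 sources. Neuronal, synaptic and axon guidance genes were LAD in mES cells and not in heart in 16 regions and the reverse in 3 (exact sign test p = 0.00443, adjusted p = 0.083). Erbb4, Epha7 and Pcdh7 of those genes were open in heart, and the other 13 were in no heart list. None of these sign tests on regions passed after adjustment. Such tests expect leaving and entering equally often. Of all protein-coding genes, 1003 were LAD in mES cells and not in heart and 530 the reverse. The neuronal excess of 13 regions did pass with 20 kb trimmed from domain ends (20 regions, adjusted p = 0.00231, exact sign test) and without chromosome 2 or 6 (14 regions each, adjusted p = 0.0328 and 0.0246, exact sign tests). It was 3 regions against 1 among genes listed in all 3 sources. By gene, 3 of 50 neuronal genes left the LADs in that set, compared with 13.6% of other genes (Fisher exact test, adjusted p = 0.552). Leaving the LADs was thus not shown to be more common in this list than in other genes. Between KOD and open, the endothelial genes Tie1, Flt1, Fli1 and Postn were KOD in mES cells and open in heart, and Pecam1 the reverse. With genes that came from or went to another state or no list, 5 endothelial regions became open and 3 ceased to be (exact sign test p = 0.727).

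In all 3525 of 17953 protein-coding genes listed in both maps changed state from mES cells to heart, 1969 of them from open to KOD and 799 from KOD to open. Examples of the first kind were Lin28a, Gata4, Gata6, the homeobox genes Dlx1 and Dlx2, and Polr2a, Tuba1b and Hnrnpk of the housekeeping list. Examples of the second were Irx5, Emx1, Myod1, Ddx4, Dlk1 and Rtl1. Without chromosome 11 the open to KOD count was 1554. With 20 kb trimmed from every domain end 1710 genes changed state, so at least part of the count lies near domain edges. Actc1, Isl1, Ryr2 and Col3a1 then no longer counted as LAD in mES cells, nor Nebl, Mef2c, Erbb4, Hbb-bt, Hbb-bs and Alb as open in heart, nor Dppa4 and Myom2 as LAD there. Of the KOD and open examples, Gata4, Polr2a and Tuba1b then were in no list in heart, and Gata6, Irx5 and Dlk1 in no list in mES cells.

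Between mES cells and forebrain, single genes of neurons and of the forebrain were LAD in mES cells only, and single pluripotency genes were LAD in forebrain only when these 2 maps are compared. Map2, the dendritic microtubule protein (chromosome 1), Nfia, a transcription factor of the developing brain, Lmx1a, Epha7 and Pcdh17 were LAD in mES cells and open in forebrain. Opcml and Dcc, the netrin receptor, were LAD in mES cells and KOD in forebrain. Zfp42, also known as Rex1, and Dppa2 and Dppa4 were wholly open in mES cells and wholly LAD in forebrain, and Grin2b and Apob went from KOD to LAD. With 20 kb trimmed from every domain end Pcdh17, 50.6% LAD and then 53.2% open, was in no list in either source, and the other genes named here had the same states. Lmx1a was LAD over 49.1% of its body in mES cells, and its midpoint did not show the change.

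By list the neuronal genes left the LADs in 8 regions and entered them in 4 (p = 0.388, exact sign test), the forebrain transcription factors in 3 and 0 (p = 0.25, exact sign test) and the pluripotency genes in 0 and 2 (p = 0.5, exact sign test), and none of these sign tests passed the threshold. All 3 pluripotency genes LAD in forebrain had not been LAD in mES cells, compared with 19.9% of other genes (Fisher exact test, adjusted p = 0.0453, and 0.038 among genes listed in all 3 sources). The absence of the list from the LADs of mES cells fixes this share. More genes went from open to KOD, 2406, than from KOD to open, 1119, among 4149 of 18328 genes that changed state. Without chromosome 11, where KOD covered 21.4% of bases in mES cells and 39.0% in forebrain, the first count was 1868. The open to KOD group took in Actb, Polr2a, Tuba1b and Psmb2 of the housekeeping list (8 regions ceased to be open and 1 became open, exact sign test p = 0.0391, adjusted p = 0.195, and an excess of 11 regions with 20 kb trimmed, adjusted p = 0.0366) and 6 of the 25 genes of H3K9 methylation and the nuclear lamina, namely Setdb1, Cbx1, Cbx3, Cbx5, Prr14 and Banf1 (exact sign test p = 0.0312, adjusted p = 0.195). Neither list ceased to be open more often than other genes, with 8 of 36 and 6 of 24 compared with 23.5% for each (Fisher exact p = 1 and 0.812). It also held Emx2, Lhx2 and Dlx1, transcription factors of the forebrain itself, as well as Gata4, Tbx2, Myl2, Tpm1, Sox9 and Col1a1. Myh7, Mybpc3, Tie1, Erg, Fli1, Postn, Runx2 and Emx1 went from KOD to open. With 20 kb trimmed, 2385 genes changed state, and Setdb1, Cbx5, Lhx2, Myh7 and Mybpc3 were in no list on 1 of the sides. Hox genes were open in mES cells in 39 of 39 cases and KOD in forebrain in 16, but these 16 lay in 5 regions (exact sign test p = 0.0625, adjusted p = 0.276). Among genes listed in all 3 sources, 20.5% of other genes ceased to be open (Fisher exact test, adjusted p = 0.0264, with genes of a cluster taken as independent).

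Between forebrain and heart, a part of the heart muscle genes and the 4 beta-globin genes were LAD in forebrain, as in mES cells, and open in heart. Of the cardiac contractile list 30 of 45 genes were open in heart, 10 were LAD in forebrain and 10 in mES cells. Actc1, Ryr2, Slc8a1, Nebl and Corin, the transcription factors Tbx18, Isl1 and Zfpm2, Tek, the angiopoietin receptor of endothelial cells, Col3a1, Alb and Afp and the 4 beta-globin genes were LAD in forebrain and open in heart. The region of Ryr2 that differed ran from 11530001 to 11970000 on chromosome 13 and that of Slc8a1 from 81360001 to 81770000 on chromosome 17. They were among the 5 longest of those LAD in forebrain and open in heart, with chromosome 5 from 10880001 to 11920000 (Speer1), chromosome 14 from 44150001 to 44680000 (Gm5930) and chromosome 4 from 60400001 to 60840000 (the Mup genes of urinary proteins). The longest in the other direction lay in Ctnnd2 (chromosome 15, 30270001 to 30750000), in the Psg gene cluster (chromosome 7, 18410001 to 18830000) and in Dpp6 (chromosome 5, 26870001 to 27130000). Map2 was open in forebrain and LAD in heart, and Opcml and Dcc KOD in forebrain and LAD in heart.

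From forebrain to heart, genes of the cardiac contractile list were no longer LAD in 6 regions and newly LAD in 1 (p = 0.125, exact sign test), and cardiac transcription factors in 4 and 0 (p = 0.125, exact sign test). For the neural crest, mesenchyme and skeletal muscle list it was 4 and 0 (p = 0.125, exact sign test) and for the blood list 3 and 0 (p = 0.25, exact sign test). For the neuronal list it was 13 and 4 (p = 0.049, exact sign test, adjusted p = 0.46). None of these sign tests passed after adjustment. Of all protein-coding genes, 929 were LAD in forebrain and not in heart and 442 the reverse, while the sign test expects equal numbers. The neuronal excess of 9 regions rose to 21 when both ends of a gene had to be in 1 state and then passed (exact sign test, adjusted p = 0.00195). It was 2 regions against 3, in the other direction, among genes listed in all 3 sources. In that set 2 of 47 neuronal genes left the LADs, compared with 9.05% of other genes (Fisher exact p = 0.434). Counted by gene, 6 of 8 blood genes and 4 of 4 of the neural crest, mesenchyme and skeletal muscle list left the LADs, compared with 27.1% of other genes (Fisher exact test, adjusted p = 0.0414 and 0.0372), and the second did not pass among genes listed in all 3 sources. The 6 blood genes lay in 3 regions, and 4 of them are the adjacent beta-globin genes. No gene of the second list was LAD in heart, 0 of 19, which fixes its share. The midpoints of Nebl, Corin, Zfpm2 and Pcdh7 did not show the change from LAD to open. A total of 2721 of 17903 genes changed state, 1162 from KOD in forebrain to open in heart and 981 from open to KOD. Actb, Psmb2, Cbx1, Cbx5, Emx2, Lhx2, Otx2 and Sox9 were in the first group, and Klf4, Gata6, Erg, Ywhaz and Lbr in the second. With 20 kb trimmed from each domain end the total was 1003. Actc1, Tbx18 and Nebl then no longer counted as LAD in forebrain, nor Zfpm2, Erbb4, Alb, Hbb-bt and Hbb-bs as open in heart, nor Map2 and Opcml as LAD there. Cbx5 and Lhx2 were then in no list in forebrain, and Lbr in none in heart.

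What lost LADs turn into was asked for each ordered pair of sources. The SE of a difference here is not a jackknife. It is that of the unweighted mean over chromosomes, while the difference itself is taken over all bases. Where a LAD of mES cells was another listed state in forebrain (72.0 Mb, the Dcc and Opcml genes included), 60.5% ± 12.4 of the bases were KOD, compared with 35.6% ± 2.51 of all bases listed as KOD or open in forebrain, a difference of 24.9 points (SE 4.73, higher on 17 of 19 chromosomes, adjusted p = 6e-05, two-sided permutation test). The bases compared with include the lost LAD bases and leave out those in no list. The difference was 32.4 points (SE 1.75) from heart to mES cells, 30.3 points (SE 3.21) from heart to forebrain and 15.1 points (SE 2.06) from forebrain to mES cells, each higher on 19 of 19 chromosomes with an adjusted permutation p = 6e-05. In heart, where Actc1, Ryr2 and the beta-globin genes went from LAD to open, 46.9% ± 7.45 of the LAD bases of mES cells that were in another listed state were KOD and 53.1% open. The excess of KOD over other bases was 8.65 points from mES cells to heart (SE 4.84) and 6.78 points from forebrain to heart (SE 4.33), and neither passed the test (adjusted p = 0.138 for each, permutation test). Against only those KOD or open bases that lie outside the LADs of the first source but within 100 kb of one, the differences were 25.2 and 26.9 points (adjusted p = 3e-05 for each, permutation test). With each chromosome left out, the difference from mES cells to forebrain against all bases listed as KOD or open ranged from 22.0 to 36.6 points. The highest was without chromosome 7.

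Gene density and gene families of the states were compared with the same maps. Open domains held 17.2 ± 0.716 protein-coding genes per Mb in mES cells, 16.7 ± 0.765 in heart and 15.9 ± 0.606 in forebrain, and LADs 3.25 ± 0.502, 3.04 ± 0.435 and 3.23 ± 0.403. KODs lay between, with 6.35 ± 0.557, 8.31 ± 0.980 and 9.45 ± 1.22. The ratio of open to LAD was 5.30 ± 0.751, 5.51 ± 0.682 and 4.92 ± 0.524. Without olfactory and vomeronasal receptor genes it was 8.30, 8.71 and 7.16. Of 20661 protein-coding genes, 13131 were open, 3401 LAD and 2675 KOD in mES cells, 11986, 2928 and 3684 in heart, and 11856, 3415 and 3901 in forebrain.

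Olfactory receptor genes, the largest family tested, were LAD in 935 of 1104 cases in mES cells, 919 in heart and 918 in forebrain (84.7%, 83.2% and 83.2%, compared with 12.6%, 10.3% and 12.8% of other genes). Neuronal, synaptic and axon guidance genes were LAD in 64 of 87 cases in mES cells, 51 in heart and 60 in forebrain, among them Cntnap2, Csmd1 and Dlg2 in all 3. Vomeronasal receptor genes, which serve pheromone sensing, were LAD in 306 of 352 cases in mES cells. Keratin genes were KOD in 38 of 49 cases in mES cells and 48 in heart. Pluripotency genes were open in 26 of 29 cases in mES cells, Hox genes in 39 of 39, housekeeping genes in 36 of 37, genes of H3K9 methylation and the lamina in 24 of 25, ribosomal protein genes in 71 of 76 and Zfp genes of zinc finger proteins in 293 of 360. Each count named so far in this paragraph passed both the Fisher exact test against other genes and the permutation test by shifts, each adjusted over 225 tests. In total 54 of 225 counts passed. The shift test treats a list as if it could lie anywhere on the chromosome, and on simulated lists of neighbouring genes both tests together passed in 17% of lists with no enrichment, against 1.5% when lists were rotated along the order of genes. Of the 54, 40 passed that rotation too, a test chosen after the data were seen, and all the counts named here are among them. Some of these counts depend on other choices, where the larger adjusted p of the Fisher exact and the shift permutation test is given. The neuronal count in heart was lost in 9 of the 19 maps with 1 chromosome left out, with 20 kb trimmed from domain ends (Fisher exact or permutation p = 0.152) and when both ends of a gene had to be in 1 state (32.2% LAD, p = 0.881), and that in mES cells with the last of these (48.3% LAD, p = 0.0779). Both keratin counts were lost without chromosome 11 (Fisher exact or permutation p = 0.14 in mES cells and 0.13 in heart) or chromosome 15 (p = 0.279 and 0.196). The Hox count was lost without chromosome 2, 6 or 15, although 100% of the genes left were open (Fisher exact or permutation p = 0.0528, 0.0677 and 0.063).

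Other counts did not hold under the rotation. Hox genes open in heart, 34 of 39, had an adjusted p = 0.0235 by shifts and 0.197 by rotation (permutation tests), and replication-dependent histone genes open in mES cells, 64 of 67, had 0.0096 and 0.0506. For the absence of pluripotency genes from the LADs of mES cells, 0 of 29, the rotation gave an adjusted permutation p = 0.0525. Zfp genes were open in 232 of 360 cases in forebrain, with an adjusted permutation p = 0.291 by rotation. The KOD count of the neural crest, mesenchyme and skeletal muscle list in forebrain, 8 of 19 with Sox9, Pax3 and Col1a1, had an adjusted permutation p = 0.0752 by rotation. Histone genes were KOD in 54 of 67 cases in forebrain, 7 in heart and 3 in mES cells, but the forebrain count missed the shift test (adjusted p = 0.0727, permutation), passed the rotation (adjusted p = 0.0471, permutation), and the 51 genes that ceased to be open lay in 4 regions (exact sign test p = 0.125).

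The remaining lists are given by count. Forebrain transcription factors were open in 31 of 48 cases in mES cells, 37 in heart and 33 in forebrain, and the heart count passed both tests and the rotation. It was lost against genes without olfactory and vomeronasal receptors (adjusted p = 0.078) and without chromosome 4 (0.0579) or 11 (0.0633), each the larger p of the Fisher exact and permutation tests. Cardiac transcription factors were open in 16, 19 and 13 of 30, endothelial genes in 11, 13 and 13 of 21, blood genes in 8, 12 and 7 of 18, liver and gut genes in 18, 19 and 17 of 33, and germline genes in 18, 11 and 12 of 26, in mES cells, heart and forebrain. In the same order imprinted genes were open in 12, 14 and 15 of 24 cases and interleukin, chemokine and interferon genes in 35, 35 and 36 of 82. None of these counts passed both tests. Among genes listed in all 3 sources, 7 of 15 germline genes open in mES cells ceased to be open in heart and 7 in forebrain. For other genes it was 17.0% and 20.5% (Fisher exact test, adjusted p = 0.0412 and 0.0819). By region this germline change was 7 against 1 in each tissue and did not pass (exact sign test, adjusted p = 0.352). Taste receptor genes were LAD in 29, 30 and 30 of 38 cases and beta defensins in 23, 22 and 22 of 42, and Cyp2, Cyp3 and Cyp4 genes of drug and steroid oxidation in 44, 39 and 31 of 76. None of these LAD counts passed the shift test, while by rotation the taste receptor counts passed in all 3 sources (adjusted permutation p = 0.038, 0.0121 and 0.0166) and the Cyp counts in mES cells and heart. Cyp genes were open in 6 of 76 cases in heart, fewer than other genes by both tests, but not without chromosome 4 or 19. Clustered protocadherin genes were open in 57 of 57 cases in mES cells, 56 in forebrain and 26 in heart, where 11 were LAD and 20 in no list. These lie side by side on chromosome 18 and the 31 that ceased to be open in heart made up 2 regions (exact sign test p = 0.5).

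**Figure D3:**
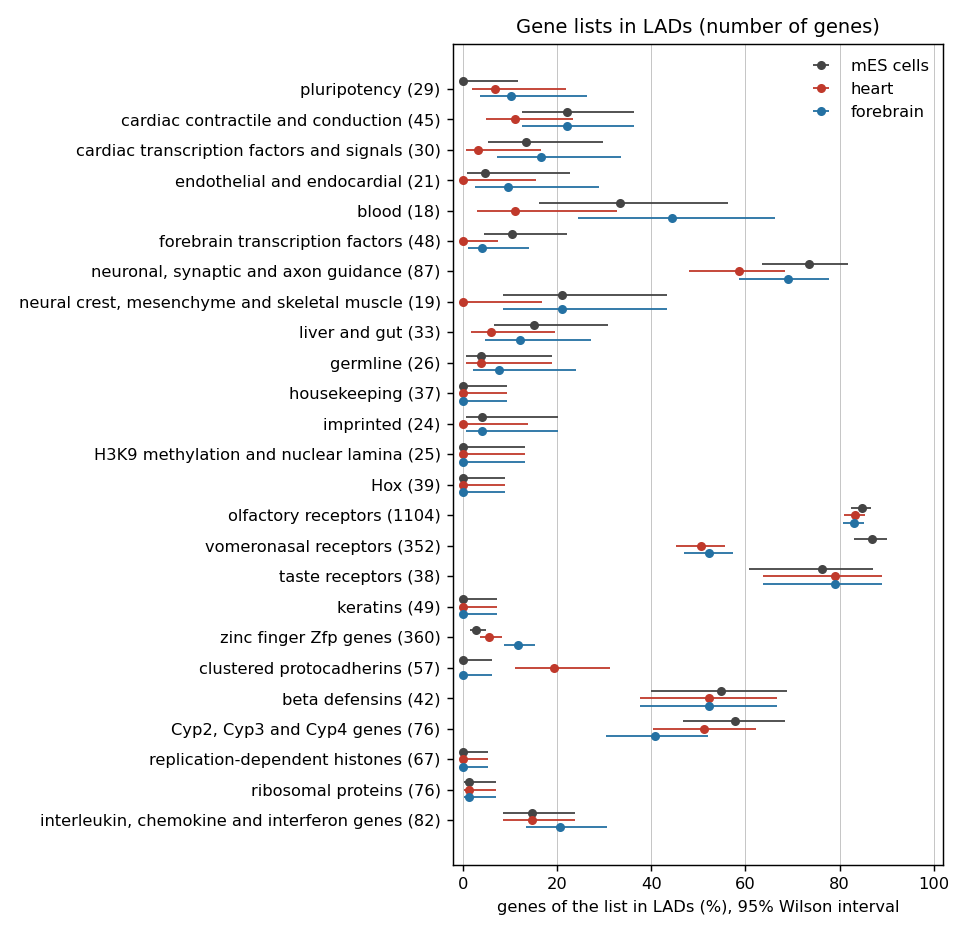
Share of the genes of each of the 25 lists that were LAD in mES cells, heart and forebrain, in percent, with 95% Wilson intervals and the number of genes in brackets; the intervals take genes as independent, which neighbouring genes are not. Olfactory receptors lie at 83.2% to 84.7% in all 3 sources and vomeronasal receptors at 86.9% in mES cells, 50.6% in heart and 52.3% in forebrain.

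Of the 25 lists 3 had more regions leaving a state than entering it, or the reverse, after adjustment over 75 sign tests per state, namely vomeronasal receptors, Zfp genes and ribosomal protein genes. The sign test sets leaving against entering within a list, so a list that starts almost wholly open can pass when its genes leave as often as others do. It expects both directions equally often. Of all protein-coding genes, however, 1003 were LAD in mES cells and not in heart and 530 the reverse. From forebrain to heart it was 929 and 442, and from mES cells to forebrain 668 and 682. A LAD sign test into heart can thus pass in part because fewer genes are LAD in heart. The sign test also takes regions as independent, though gaps in no list can split 1 gene cluster into neighbouring regions. Shares of genes were therefore also compared with other genes by Fisher exact tests, of which 72 of 300 passed after adjustment, 45 of them also among genes listed in all 3 sources, with genes taken as independent. Vomeronasal receptor genes left the LADs in 36 regions and entered them in 11 from mES cells to heart (exact sign test p = 0.000346, adjusted p = 0.013) and in 33 and 11 from mES cells to forebrain (exact sign test p = 0.00126, adjusted p = 0.0315). That is 146 and 142 of 306 genes, compared with 27.7% and 17.0% of other genes (Fisher exact test, adjusted p = 2.95e-11 and 1.41e-27). They became open in 18 regions and ceased to be in 3 from mES cells to forebrain (exact sign test, adjusted p = 0.0186), and ceased to be open in 19 regions and became open in 1 from forebrain to heart (exact sign test, adjusted p = 0.0015). The difference lay on chromosome 7, where 165 of 178 of these genes were LAD in mES cells, 36 in heart and 33 in forebrain, and 3, 87 and 114 were open. On the other chromosomes 141, 142 and 151 were LAD. Chromosome 7 as a whole also differed, with 43.4%, 34.5% and 25.7% of its bases in LADs in mES cells, heart and forebrain and 34.3%, 37.3% and 44.9% open. A region of 1250 kb from 20350001 to 21600000 on chromosome 7 was LAD in mES cells and open in both tissues and held 34 protein-coding genes, Vmn1r100 and Vmn1r101 among them, and another from 7840001 to 8550000 was open in forebrain and held Vmn2r36 and Vmn2r41. Near-identical copies share reads, so the placement of these genes is uncertain. Without chromosome 7 the excess of regions that left the LADs was 3 from mES cells to heart and -3 from mES cells to forebrain, and that of regions that ceased to be open from forebrain to heart was 3 (exact sign test, adjusted p = 0.852). Both LAD changes were also lost without chromosome 17, and that to forebrain without chromosome 5 and with 20 kb trimmed (exact sign tests, lowest adjusted p = 0.0633). Among genes listed in all 3 sources the LADs were left in 10 regions against 1 and 12 against 1 (adjusted p = 0.293 and 0.256, exact sign tests). The gain of open from mES cells to forebrain was then 11 regions against 1 (adjusted p = 0.0952, exact sign test) and the loss from forebrain to heart 3 against 0 (adjusted p = 0.67, exact sign test), so none of the 4 sign tests passed there. By gene, 82 and 86 of 231 left the LADs in that set, compared with 11.3% and 8.23% of other genes, and both passed (Fisher exact test, adjusted p = 3e-18 and 2.27e-28, genes of a cluster taken as independent).

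Zfp genes, many of which encode repressors of transposable elements, ceased to be open in 68 regions and became open in 9 from mES cells to heart (exact sign test, adjusted p = 1.84e-10), in 53 and 19 from mES cells to forebrain (exact sign test, adjusted p = 0.00189) and in 54 and 27 from forebrain to heart (exact sign test, adjusted p = 0.0385). By gene 114 of 293, 81 of 293 and 73 of 232 ceased to be open, compared with 20.3%, 23.4% and 14.5% of other genes (Fisher exact test, adjusted p = 1.69e-11, 0.224 and 2.78e-09). From mES cells to forebrain they were thus not shown to differ from other genes. None of these 3 passed among genes listed in all 3 sources (Fisher exact test, adjusted p = 0.0703, 0.157 and 0.97). From mES cells to forebrain they entered the LADs in 22 regions and left them in 2 (exact sign test, adjusted p = 0.00269). The 4 longest regions open in mES cells and LAD in forebrain all lay on chromosome 2 between 174930001 and 178090000, with Zfp968, Zfp966, Zfp973, Zfp972 and Zfp931 in them or at their edges. Gaps in no list split this stretch, so 1 cluster counts as more than 1 region in the sign test. Without chromosome 2, regions leaving minus entering the LADs were -13, against -20 with all chromosomes. The call from forebrain to heart was lost in 10 of the 19 maps with 1 chromosome left out, with 20 kb trimmed and with both gene ends in 1 state, and that of the entry into LADs without chromosome 17 (exact sign test, adjusted p = 0.083). In heart 92 of the 360 genes were in no list, 26 in forebrain and 35 in mES cells. Among genes listed in all 3 sources the change of open from mES cells passed in both tissues (37 regions against 8 in heart and 41 against 9 in forebrain), while that from forebrain to heart was 19 against 23, in the other direction, and the entry into LADs 8 against 0 (exact sign test, adjusted p = 0.293). By gene, 34 of the 42 Zfp genes LAD in forebrain had not been LAD in mES cells, compared with 19.2% of other genes (Fisher exact test, adjusted p = 3.55e-16). This passed among genes listed in all 3 sources as well (12 of 19, Fisher exact test, adjusted p = 9.51e-09). Only 10 of the 360 Zfp genes were LAD in mES cells, and 7 among those listed in all 3 sources. This fixes most of the first share, and the second is the lowest it could be, so neither adds support.

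Ribosomal protein genes ceased to be open in 15 regions and became open in 1 from mES cells to heart (exact sign test, adjusted p = 0.00973) and in 17 and 2 from mES cells to forebrain (exact sign test, adjusted p = 0.0109). They were open in 71 of 76 cases in mES cells, 56 in heart and 54 in forebrain, and KOD in 3, 18 and 19. They did not leave the open state more often than other genes, with 16 of 71 compared with 20.7% in heart and 19 of 71 compared with 23.5% in forebrain (Fisher exact p = 0.662 and 0.486), so the direction is not shown to be particular to this list. Both sign tests passed among genes listed in all 3 sources, with 13 regions against 0 and 16 against 2. Both were lost without chromosome 11 (exact sign tests, adjusted p = 0.108 in heart and 0.0837 in forebrain), and that in forebrain also without chromosome 17 (exact sign test, adjusted p = 0.0523). Olfactory receptor genes, by contrast, left and entered the LADs in 27 and 22 regions from mES cells to heart (exact sign test p = 0.568) and in 18 and 20 from mES cells to forebrain (exact sign test p = 0.871).

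**Figure D4:**
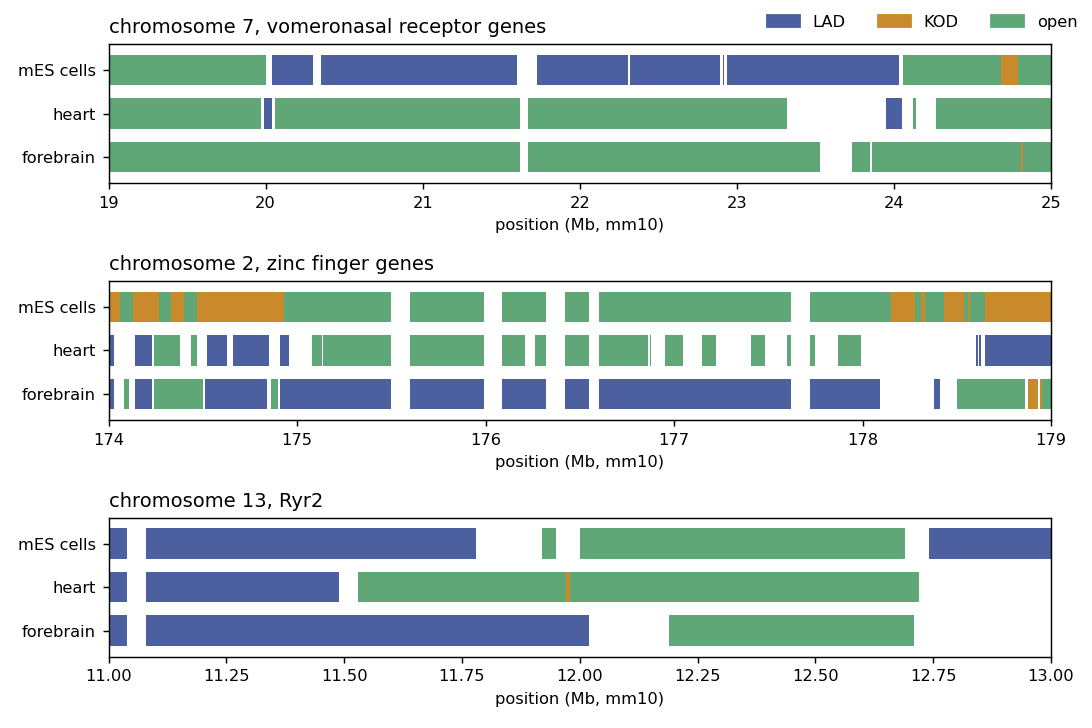
Domains along 3 regions of chromosomes 7, 2 and 13 in mm10 (position in Mb along the horizontal axis), with 1 track per source, coloured as LAD, KOD or open, and white where a bin is in no list. The stretch from 20350001 to 21600000 on chromosome 7 is LAD in mES cells and open in both tissues, that from 176600001 to 177620000 on chromosome 2 is open in mES cells and LAD in forebrain, and Ryr2 from 11553099 on chromosome 13 is LAD over 84.3% of its length in forebrain and open over 98.2% in heart.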

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

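All tests that weigh an explanation here were chosen after the result was seen; the differences themselves come from planned tests.

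The share of LAD bases differed between the embryonic tissues, by -3.91 percentage points in heart against forebrain. The heart LADs were also more numerous and shorter. Of the bases LAD in mES cells and forebrain but not in heart (121 Mb), 71.6% ± 3.27 were in no heart list, so most of the missing LAD bases were left unassigned and not moved to another state; for the bases missing from mES cells or forebrain alone the same share was 51.0% ± 2.75 and 34.1% ± 3.57. This may reflect depth or thresholds in the heart libraries or a mixture of cell types in a whole heart, which cannot be separated without values per library. A biological part remains open. Genes of the cardiac, endothelial and blood lists that were LAD in mES cells and forebrain were KOD or open in heart in 7 regions against 7 genes still LAD. For other genes it was 90 regions against 2223 genes (two-sided Fisher exact p = 4.77e-07, with only the switched genes merged into regions). The test cannot decide this part. The switched genes were already named above, regions are set against single genes, and genes in no heart list were left out. With 20 kb trimmed from domain ends Actc1, Isl1, Ryr2, Nebl, Hbb-bt and Hbb-bs lost the change. The midpoints of Ryr2, Nebl and Corin did not show it.

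From forebrain to heart, vomeronasal receptor genes ceased to be open in more regions than became open, by 18 but by 3 among genes listed in all 3 sources, and from mES cells to either tissue they left the LADs, a change that did not pass the sign test on regions among those genes either. On chromosome 7 122 of the 165 genes LAD in mES cells were LAD in neither tissue (73.9%). A change of the whole family is argued against, because on the other chromosomes 5 of 141 were, a difference of -11.3 points (SE 3.26) from genes outside tandem arrays. Chromosome 7 as a whole may contribute, because 19.9% of its LAD bases of mES cells over 200 kb from these genes were LAD in neither tissue, 13.7 points above the mean of the other chromosomes (SD 4.10, highest 16.5% on chromosome 19), which is less than the share of the genes themselves and has no known cause here. This difference was clearer in forebrain, with 35.9% of such bases not LAD there against a mean of 10.0% (SD 6.33). In heart it was 26.9% against 17.8% (SD 4.73), below the 31.8% of chromosome 19. Arrays without vomeronasal or olfactory receptors, compared first, left the LADs more often than genes outside arrays by 7.75 points (SE 5.74), and after that value was seen the comparison was changed to take in olfactory arrays, which gave -5.97 points (SE 3.32), so the sign depends on the definition, neither value decides, and reads shared between near-identical copies stay open.

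Zfp genes ceased to be open from forebrain to heart in more regions than became open, by 27, a difference between the tissues that was -4 among genes listed in all 3 sources.

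Most changed bases exchanged KOD and open in every pair of sources. If a single cut-off of H3K9me2 divided KOD from open, a looser one in 1 of the tissues would move bases almost only 1 way. In the pair with the least balance 37.4% ± 5.11 of exchanged bases went in the less common direction, which argues against such a cut-off as the whole cause. How the 2 states were divided is not given, so other effects of thresholds stay open. Edges placed differently stay open, since 38.1% ± 2.35 of exchanged bases between forebrain and heart and 60.8% ± 1.90 between mES cells and forebrain lay in regions of at least 100 kb. Background cleavage at gene-dense chromatin could not be decided for the forebrain, where bases open in mES cells and KOD in forebrain held -0.571 genes per Mb (SE 1.34) relative to bases open in both; in heart that difference was -4.70 (SE 0.980). A difference between cell states in H3K9me2 itself may account for the rest and was not tested here.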

How the results depend on the processing

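The alternatives with bins in no list as a state, the state at the gene midpoint, genes with both ends in 1 state, genes listed in all 3 sources and lists rotated along the gene order were chosen after the results were seen, and the others were planned. No paired analysis was possible because the lists pool the replicates and carry no replicate number. Leaving out a replicate was not possible for the same reason, and leaving out chromosome X was void. Depth per library is unknown, so no value here says how far it limits the maps. The lower LAD share of the heart kept its direction and its side of the threshold with short domains left out, with ends trimmed and with each chromosome left out, but not over bins listed in all 3 sources, where the missing bases are removed by construction. The overlaps kept theirs under every alternative run, but the order of the states did not, since between forebrain and heart LADs had the lowest share of domains with at least 50% in the same state (0.609). The cause was not tested for any other shift below.

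With domains under 100 kb left out, KOD in mES cells covered 15.3%, open domains 26.8% in heart and 28.5% in forebrain, and no list 12.4%, 19.6% and 13.9% in mES cells, heart and forebrain. Open in heart then differed by -3.04 points from mES cells (adjusted permutation p = 0.00663) and by -1.66 from forebrain (adjusted permutation p = 0.0178). The changed share was 14.1%, 15.9% and 10.6% for mES cells to heart, mES cells to forebrain and forebrain to heart, and the second exceeded the first by 1.82 points (adjusted permutation p = 0.0169). In mES cells, heart and forebrain there were 1182, 1740 and 1177 LADs, 1220, 1232 and 1088 KODs and 1964, 2142 and 2027 open domains. With 20 kb trimmed from domain ends, KOD covered 13.9% in mES cells and 14.5% in heart, LADs 35.3% in heart, open domains 27.1%, 24.0% and 25.8%, and no list 18.3%, 26.1% and 19.4%. The open differences were -3.01 (adjusted permutation p = 0.00492) and -1.76 points (adjusted permutation p = 0.0117). The changed shares were 11.8%, 13.5% and 8.38%, with 1.72 points between the first pair of them (adjusted permutation p = 0.0144). Genes that changed state, went from open to KOD and from KOD to open numbered 1710, 983 and 346 from mES cells to heart, 2385, 1437 and 587 from mES cells to forebrain, and 1003, 341 and 436 from forebrain to heart.

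Over bins listed in all 3 sources, KOD covered 19.6% in mES cells, LADs 46.3% in heart, open domains 34.0%, 32.0% and 33.9%, and no list 0% in each of the 3, and LADs in heart differed by -0.148 points from mES cells and 0.504 from forebrain (adjusted p = 0.78 for each, permutation test). With changed regions of at least 50 kb only, the changed shares were 14.2%, 15.9% and 10.7%, with a difference of 1.69 points (adjusted permutation p = 0.00674). With bins in no list as a state they were 27.4%, 26.6% and 24.9%, and forebrain to heart differed from mES cells to forebrain by -1.75 points (adjusted permutation p = 0.0955). Against bases within 100 kb of a LAD the KOD excess was 25.2 points from mES cells to heart and 26.9 from forebrain to heart. With genes of all types, LADs held 10.4, 9.98 and 10.6 genes per Mb, KODs 19.3, 21.9 and 23.4 and open domains 32.0, 31.0 and 29.9, with ratios of 3.07, 3.10 and 2.83. Without olfactory and vomeronasal receptor genes, LADs held 2.07, 1.90 and 2.19 and the ratios were 8.30, 8.71 and 7.16.

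Of the 54 list calls, 31 held with a background without these receptors and 12 were lost, while the 11 of the receptors themselves could not be tested there, 43 held and 11 were lost with ends trimmed, 42 and 12 with genes with both ends in 1 state, and 40 and 14 by rotation, with 23 gained. Among genes listed in all 3 sources the one-sided changes numbered 0 for LADs and 4 for open, and the Zfp difference in open from forebrain to heart was -4. Apart from maps with a chromosome left out, the sign tests gained were neuronal LAD from mES cells to heart (20 regions) and housekeeping open from mES cells to forebrain (11) with ends trimmed, and with both gene ends in 1 state neuronal LAD from forebrain to heart (21) and Cyp open from mES cells to heart (9). With both gene ends in 1 state, 2347 genes changed from mES cells to heart and 1594 from forebrain to heart, 441 and 659 went from KOD in mES cells to open in heart and forebrain, and 511 and 765 went from open to KOD and from KOD to open between forebrain and heart. Leaving out 1 chromosome gave 0 (without chromosome 17) to 4 one-sided LAD changes, with 1 without chromosome 7, and 4 (without chromosome 7 or 11) to 7 one-sided open changes. The vomeronasal difference from mES cells to forebrain ranged from -3 to 27 for LADs and from -17 to 2 for open, with -3 and 2 both without chromosome 7. Genes LAD in mES cells and not in forebrain ranged from 404 (without chromosome 7) to 665. Differences that passed with some chromosomes left out ranged from -1.65 to -0.848 (open, heart against forebrain), -2.22 to -1.19 (open, heart against mES cells), 1.01 to 1.96 (KOD, heart against forebrain), 0.694 to 1.24 (changed shares from mES cells) and 5.39 to 8.37 points (KOD excess, forebrain to heart).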

Other observations

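The Fisher exact tests and the ranking of regions were planned, and which of them to describe was chosen after the results were seen.

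Gene clusters stood among the longest regions that were LAD in 1 source and open in another. Between mES cells and heart the longest, on chromosome 5 from 94140001 to 95780000, held 22 protein-coding genes, Pramel38 and Pramel41 of the Prame family among them, and was LAD in mES cells and open in heart. The Speer region of chromosome 5 from 10880001 to 11920000 was LAD in mES cells and forebrain and open in heart. On chromosome 7 the Obox genes, homeobox genes of the oocyte, lay from 15000001 to 15680000 in a region LAD in mES cells and open in forebrain, and the Psg genes, pregnancy-specific glycoproteins, from 18410001 to 18830000 in one LAD in heart and open in forebrain. Near-identical copies make the placement of reads in these clusters uncertain.

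Of the genes LAD in mES cells, olfactory receptor genes left the LADs in 56 of 935 cases in heart and 47 of 935 in forebrain, compared with 38.4% and 25.2% of other genes (Fisher exact test, adjusted p = 4.24e-90 and 2.29e-46), and taste receptor genes in 0 of 29 in either tissue, compared with 29.7% and 19.8% (Fisher exact test, adjusted p = 0.000496 and 0.0246). Genes that leave for no list count here. Among genes listed in all 3 sources, a set chosen after the results were seen, the share of other genes set against taste receptors was 13.6% and 10.9% and neither difference passed (Fisher exact test, adjusted p = 0.149 and 0.323), while both of the olfactory receptors did. All 5 forebrain transcription factor genes that were LAD in mES cells, namely Neurod1, Neurod6, Lmx1a, Isl1 and Nfia, were not LAD in heart (Fisher exact test, adjusted p = 0.0176). No gene of this list was LAD in heart, 0 of 48, which fixes this share. Isl1 and Nfia were open there and the others in no list, and with only the 2 of the 5 listed in all 3 sources the test did not pass (Fisher exact test, adjusted p = 0.108). These tests take genes as independent, which those of a cluster are not.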
